A study of Lactuca serriola with 12 samples.

How the data were processed

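Roots of Lactuca serriola were sampled from plants held at 22 °C with 12 h of light and 12 h of dark for 34 days, per the labels' protocols, with drought given as 6 days without water. RNA was extracted with a column kit, ribosomal RNA was depleted with a plant rRNA kit, and strand-marked total RNA libraries were made, per the labels' protocols. The deposited table holds whole-number counts per gene for 12 libraries, and its column totals differ between libraries, so the values were treated as raw counts. Trimmomatic, HISAT2 and StringTie are named in the submitters' processing notes; their versions, settings, the genome build and the way the counts were made are not given in the sources used here. The count value 3 was from 0.893 to 1.16 times as common as 2 in the 12 libraries, while 4 was from 0.511 to 0.641 times as common as 3 and 2 from 0.726 to 0.967 times as common as 1. Counts of reads usually fall more evenly, so the deposited counts may not equal numbers of reads, and totals are those of the table. Whether the authors counted by strand is not given in the sources used here, so overlapping and antisense genes are uncertain.

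The table has 51651 entries, of which 16336 are at 0 in every library. The 7 entries without a gene name were left out of library sizes and tests; they held from 0.00332% to 0.803% of a library's counts. Nuclear genes carry LOC identifiers (50535 entries), 0 of which are in the gene table used here for names (assembly Lser_US96UC23_V15), so the files do not pair them with descriptions. Of 1109 entries with another symbol, 1096 are in that table, which was used only for symbols and for the organelle genome a symbol belongs to. Of 43 gene lists fixed before the data were examined by patterns on descriptions and symbols, 42 had no tested member and gave no result; they covered stress hormones, osmolytes, defence, transcription factors, cell walls, nutrition and markers of other cell types. The list of organelle-encoded genes had 174 tested members. After the data were seen, 10 groups were formed from symbols: mitochondrial rRNA, mitochondrial respiratory chain and ATP synthase, mitochondrial cytochrome c maturation, plastid photosystems with cytochrome b6f and rbcL, plastid NDH complex, plastid ATP synthase, plastid RNA polymerase, organelle ribosomal proteins, organelle tRNAs and nuclear tRNA genes. Organelle genes can be copied in the nuclear genome, and rrnS, rrnL and nad5 each have more than 1 entry, so their counts are uncertain where reads could be split.

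Samples were grouped from their labels, 3 per group. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on counts with TMM scaling, the low-count filter filterByExpr (minimum count 10, minimum total 15) and robust dispersions, with all 12 libraries in 1 fit of 4 group means and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p below 0.05, and counts with an absolute log2 fold change of at least 1 were taken too. Standard errors were derived from the F statistic. Comparisons were drought in uninfected and in YJ6 roots, YJ6 under benign water and under drought, their interaction and the mean drought effect. CPM are TMM-scaled, and log2 CPM used a prior count of 2. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The list p-values were adjusted over lists of at least 5 tested members fixed before the data were examined, which left a single list, and separately over the 10 groups.

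The rule for named genes, set before the data were examined, took genes that passed the adjusted p, changed by at least 1 on the log2 scale, had a mean of at least 5 CPM in the higher group and did not overlap between groups. As the files give no names for nuclear genes, the rule allowed at most 2 identifiers higher and 2 lower per comparison, and from each list up to 4 members with the smallest p. The likeness of the 2 main comparisons was measured by correlation and covariance across genes. In 100 simulations the control libraries and those of the compared groups were all drawn from the uninfected benign means, each gene independently. Principal components used the 500 most variable tested genes, and their 2 relations with library depth and mitochondrial rRNA share were tested by permutation, 2-sided.

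The edgeR step was tested on simulated data for the YJ6 comparison under benign water: counts for about 28100 genes were drawn from the real means with 200 genes changed, in 3 runs. It recovered 61.4% of genes changed 4-fold and 7.78% of those changed 2-fold, with a mean of 3 false calls among 71.7 and 0 wrong signs. It made 0 calls where no gene was changed. Each gene was drawn independently, so these rates leave out structure that genes share within a library and may not hold for the real libraries. At this depth, from 86437511 to 395597485 counts per library, counting error is small for most genes and the spread between libraries sets the precision; no counting intervals are given. Pairs of libraries within groups were checked for copies, and every pair differed far beyond sampling noise, with a chi-square per degree of freedom of 118 or more.

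Alternatives chosen before the data were examined were DESeq2 1.42.0 (Wald test, its own filtering), DESeq2 size factors in edgeR, no filter or a filter of 10 CPM, the 10 most abundant genes left out, a fit of only the groups compared, a replicate block, and each library left out in turn. A fit with the log2 mitochondrial rRNA share as a covariate was added after the data were seen, as were other scaling and left-out libraries for the gene lists and the splits without shared controls.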

Results

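RNA was sequenced from roots of Lactuca serriola (prickly lettuce, a wild relative of cultivated lettuce) grown with or without Erwinia tasmaniensis YJ6, a bacterium that lives inside the seed. Plants of both kinds were either kept watered (benign water) or left without water for 6 days (drought), which gave 4 groups: uninfected benign, uninfected drought, YJ6 benign and YJ6 drought. Each group held 3 libraries labelled as biological replicates, 12 in all. Total counts ranged from 86437511 in YJ6 drought replicate 1 to 395597485 in uninfected drought replicate 1, and 28487 genes had enough counts to be tested. The nuclear genes carry identifiers that the files do not pair with descriptions, so single nuclear genes are given by identifier, and gene groups could be formed only for mitochondrial and plastid genes and for tRNA genes. The labels do not say whether replicates came from separate plants or pots, so the p-values measure only the spread between these libraries.

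Libraries of one group were not close to one another in overall expression. The first principal component of the 500 most variable genes took 40.4% of the variance and placed YJ6 benign replicate 1 at -24.2 and YJ6 benign replicate 3 at 70.1, a wider gap than between many libraries of different groups. The 3 uninfected benign libraries lay at -38.7, -35.1 and -27.3 on it, near uninfected drought replicate 3 at -39.6. On the second component, with 16.4% of the variance, the uninfected benign libraries were far apart, at -0.868, 48.65 and 31.32. Within groups, correlations of log2 CPM (counts scaled by effective library size) between libraries ran from 0.924 to 0.976, and between groups from 0.882 to 0.976. The 2 most abundant genes together took from 5.73% to 23.9% of a library's counts, with the highest share in uninfected benign replicate 2.

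**Figure D1:**
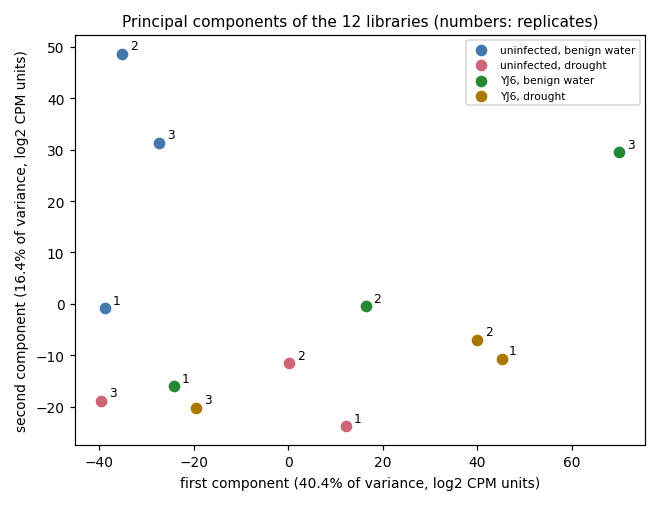
First (x axis, 40.4% of variance) and second (y axis, 16.4% of variance) principal components of log2 CPM over the 500 most variable genes; each point is 1 library, colours are the 4 groups and numbers the replicates. Libraries of the YJ6 benign group spread from -24.2 to 70.1 on the first component, while the 3 uninfected benign libraries lie between -38.7 and -27.3. On the second component the uninfected benign libraries spread from -0.868 to 48.65.

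In uninfected roots, drought raised 17 genes and lowered 15. The largest rise among genes that met the naming criteria was that of LOC111913327, from 0.283 ± 0.260 to 53.2 ± 32.5 CPM (SD, n = 3), a log2 fold change of 7.55 (SE 1.15, adjusted p = 0.0476 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). LOC111878688 rose from 1.96 ± 1.25 to 14.8 ± 1.41 CPM, a log2 fold change of 2.91 (SE 0.381, edgeR adjusted p = 0.0318). LOC111902479 fell from 5.32 ± 2.35 to 0.0696 ± 0.0254 CPM, a log2 fold change of -6.23 (SE 0.666, edgeR adjusted p = 0.0318). LOC111899651 fell from 8.11 ± 1.46 to 1.02 ± 0.443 CPM, a fall of 3.00 on the log2 scale (SE 0.453, edgeR adjusted p = 0.0476). The naming criteria required that the CPM of the 3 drought and the 3 benign libraries not overlap, so this holds for all 4 genes by selection. The 32 genes that changed had a median size of 2.22 on the log2 scale and none changed by less than 1.12. By DESeq2 the drought comparison in uninfected roots gave 604 genes higher and 528 lower, while edgeR called 0 when the mitochondrial rRNA share was added as a covariate and 0 when only the 2 groups compared were fitted. A replicate block left 19. With the covariate the 32 genes kept their direction, with a median size of 2.16 (median SE 0.440, against 0.322 without it) and an unadjusted p below 0.05 in 32 of 32. The edgeR count was 445 without uninfected benign replicate 1, 18 without YJ6 benign replicate 1, 1 without uninfected drought replicate 3 or YJ6 drought replicate 1. It was 0 without uninfected benign replicate 2 or 3, uninfected drought replicate 1 or 2, YJ6 benign replicate 2 or 3, or YJ6 drought replicate 2. Over the alternative settings, LOC111878688 stayed under an adjusted p of 0.05 in 9 of 20, LOC111913327 in 7 of 20, LOC111902479 in 9 of 19 and LOC111899651 in 6 of 19, with the same direction in each.

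As a list, genes encoded in the mitochondrion and plastid lay lower under drought in uninfected roots on TMM-scaled values, although no member passed singly by edgeR. Of 174 such genes, 162 had a log2 fold change below 0, with a median of -0.215, and the list lay below the other tested genes (camera p = 5.47e-12, adjusted p = 0.00982 with an estimated correlation). By edgeR's quasi-likelihood test 0 of the 174 passed singly, over all genes and adjusted over the list alone, with 15 at an unadjusted p below 0.05, and DESeq2 called 3 lower. The list summed to 43390 ± 2340 CPM in uninfected benign and 33480 ± 3390 CPM in uninfected drought libraries (SD, n = 3). On this TMM-scaled measure 72.6% of the difference in the sum came from 4 entries of mitochondrial ribosomal RNA, the rrnL and rrnS transcripts of the large and small ribosomal subunits, which summed to 13590 ± 4610 and 6397 ± 2810 CPM. Mitochondrial rRNA took 1.20% ± 0.199 of counts in uninfected benign and 0.669% ± 0.310 in uninfected drought libraries. The libraries were depleted of rRNA, and uneven depletion was not told apart from a change in the roots. As a share of all counts, without TMM scaling, the other organelle genes were not lower on average, at 2.76% ± 0.657 in uninfected benign and 2.81% ± 0.231 in uninfected drought libraries. Uninfected benign replicate 2 stood at 2.06%, with 23.9% of its counts in the 2 most abundant genes. Replicates 1 and 3 of that group stood at 3.36% and 2.86%, so this share does not settle the direction. The more abundant rrnS entry stood at 1417 ± 539 CPM against 554 ± 312 CPM (log2 fold change -1.36, SE 0.431, edgeR adjusted p = 0.236).

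In roots that carried YJ6, drought changed 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 1217 at an unadjusted p below 0.05 where 1424 were expected by chance. DESeq2 called 36 higher and 24 lower, and edgeR 1 gene without YJ6 drought replicate 3. LOC111913327 stood at 0.526 ± 0.265 CPM in YJ6 benign and 89.7 ± 89.8 CPM in YJ6 drought libraries, a log2 fold change of 7.40 (SE 1.13). That was close in size to the 7.55 (SE 1.15) in uninfected roots, and its edgeR adjusted p was 0.349. Adjusted p-values depend on all genes of a comparison, so this value does not show a weaker response of the gene in YJ6 roots. LOC111878688 stood at 5.81 ± 0.947 and 10.8 ± 2.01 CPM (log2 fold change 0.90, edgeR adjusted p = 0.999). LOC111902479 stood at 0.870 ± 0.424 and 0.257 ± 0.170 CPM (log2 fold change -1.79, edgeR adjusted p = 0.999). Organelle genes showed no shift that passed the test: the median log2 fold change was 0.0509, with 100 of 174 above 0 (camera p = 0.106, adjusted p = 0.453 with an estimated correlation). At the preset correlation, the camera p was 0.0342 without YJ6 benign replicate 3 and 0.0103 without YJ6 drought replicate 2. By edgeR 0 members passed singly, over all genes and adjusted over the list alone, with 4 at an unadjusted p below 0.05, and DESeq2 called 0.

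Under benign water, roots with YJ6 differed from uninfected roots in 209 genes, 86 higher and 123 lower, of which 181 changed by at least 1 on the log2 scale. LOC111913760 rose from 1.18 ± 0.193 CPM in uninfected to 38.6 ± 22.7 CPM in YJ6 roots (SD, n = 3), a log2 fold change of 5.03 (SE 0.735, adjusted p = 0.0281 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). LOC111882425 rose from 1.25 ± 0.407 to 31.9 ± 16.5 CPM, a log2 fold change of 4.68 (SE 0.890, edgeR adjusted p = 0.0475). LOC111891133 fell from 7.18 ± 4.43 to 0.0681 ± 0.0390 CPM, a log2 fold change of -6.74 (SE 1.14, edgeR adjusted p = 0.0341). LOC111898732 fell from 324 ± 223 to 8.79 ± 4.65 CPM, a log2 fold change of -5.20 (SE 0.788, edgeR adjusted p = 0.0281). Uninfected benign replicate 1 stood lower, at 66.1 CPM, than the 464 and 441 CPM of the other libraries of its group. The libraries of the 2 groups did not overlap in 24.9% of the tested genes, where chance gives 10%. That share was 15.2% for drought in uninfected roots, 10.7% for drought in YJ6 roots and 7.22% for YJ6 under drought. DESeq2 gave 1272 genes higher and 1135 lower for YJ6 under benign water, whereas edgeR called 2 genes when only the 2 groups compared were fitted and 0 with the mitochondrial rRNA share as a covariate. A replicate block left 16. With the covariate the 209 genes kept their direction, with a median size of 1.40 against 1.64 without it (median SE 0.451 against 0.279) and an unadjusted p below 0.05 in 162. The edgeR count was 919 without uninfected benign replicate 1, 411 without uninfected drought replicate 3, 131 without YJ6 drought replicate 1, and 92 without uninfected drought replicate 1. It was 64 without YJ6 drought replicate 2, 39 without YJ6 benign replicate 1, and 15 without uninfected drought replicate 2. It was 0 without uninfected benign replicate 2 or 3 or YJ6 benign replicate 2 or 3. Over the alternative settings, LOC111913760 stayed under an adjusted p of 0.05 in 12 of 20, LOC111898732 in 11 of 20, LOC111891133 in 9 of 19 and LOC111882425 in 7 of 20, with the same direction in each. With the rRNA covariate the log2 fold changes were 3.13 for LOC111913760, 2.21 for LOC111882425, -5.41 for LOC111891133 and -3.27 for LOC111898732.

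**Figure D2:**
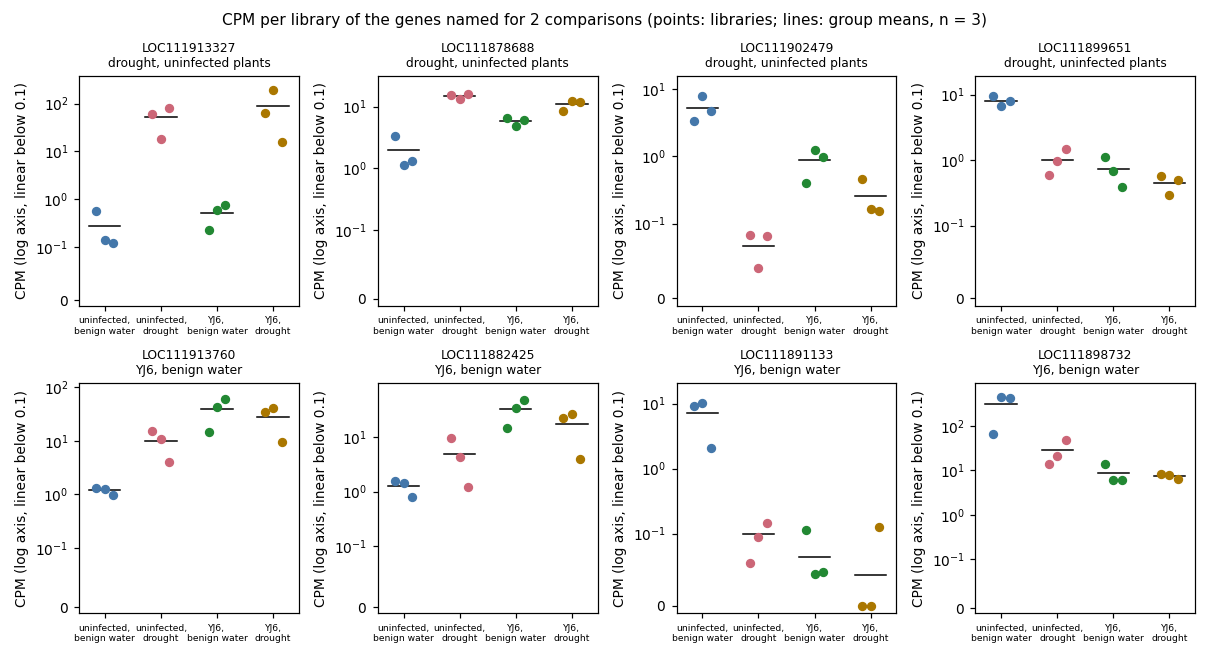
CPM per library (y axis, logarithmic above 0.1 and linear below) of the 4 genes named for drought in uninfected roots (top) and the 4 named for YJ6 under benign water (bottom); points are libraries, lines group means (n = 3). LOC111913327 is high in both drought groups and low in both benign groups, whereas LOC111899651, LOC111891133 and LOC111898732 are high in the uninfected benign group and lower in each of the other 3.

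The organelle list was also lower with YJ6 under benign water on TMM-scaled values, although no member passed singly by edgeR. The list of 174 had 147 members below 0 and a median log2 fold change of -0.273 (camera p = 6.93e-10, adjusted p = 0.0167 with an estimated correlation). By edgeR 0 members passed singly, over all genes and adjusted over the list alone, with 27 at an unadjusted p below 0.05, and DESeq2 called 9 lower. The list summed to 31040 ± 2000 CPM in YJ6 benign libraries, against the 43390 ± 2340 CPM of the uninfected benign libraries, and on this TMM-scaled measure mitochondrial rRNA made up 72.5% of the difference. As a share of all counts the other organelle genes were not lower on average, at 2.89% ± 0.302 in YJ6 benign against 2.76% ± 0.657 in uninfected benign libraries. Uninfected benign replicate 2, at 2.06%, lowered the latter mean. Replicates 1 and 3 of that group stood at 3.36% and 2.86%, so this share does not settle the direction. Mitochondrial rRNA took 0.503% ± 0.0632 of counts in YJ6 benign libraries, against 1.20% ± 0.199 in the uninfected benign libraries, and rrnS stood at 337 ± 121 CPM (log2 fold change -2.07, SE 0.440, edgeR adjusted p = 0.0585). The edgeR adjusted p of rrnS was 0.0344 without uninfected benign replicate 1 and 0.0341 without uninfected drought replicate 3. Here too, uneven rRNA depletion was not told apart from a change in the roots. Beyond organelle genes, 1 nuclear tRNA gene, TRNAP-AGG, fell from 1.02 ± 0.130 to 0.240 ± 0.0718 CPM, a log2 fold change of -2.08 (SE 0.346, edgeR adjusted p = 0.0329); it was named after its value was seen.

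Under drought, YJ6 changed 0 genes by edgeR's quasi-likelihood test, with 950 at an unadjusted p below 0.05 where 1424 were expected by chance, and DESeq2 called 11 higher and 16 lower. Without YJ6 drought replicate 3, edgeR called 1 gene. LOC111913760 stood at 9.97 ± 5.60 CPM in uninfected drought and 27.9 ± 16.1 CPM in YJ6 drought libraries (log2 fold change 1.48, SE 0.629, edgeR adjusted p = 0.990). LOC111898732 stood at 28.3 ± 19.0 and 7.51 ± 0.995 CPM (log2 fold change -1.91, SE 0.684, edgeR adjusted p = 0.990). The organelle list had a median log2 fold change of -0.0121 with 91 of 174 members below 0, while its mean was 0.00563 and camera's direction was up (p = 0.369, adjusted p = 0.672 with an estimated correlation), so the median and the test differed in sign and neither direction passed. At the preset correlation, the camera p was 0.000757 without uninfected drought replicate 3 and 0.0424 without YJ6 drought replicate 2, both up. The direction in limma's camera was down without uninfected drought replicate 1 (camera p 0.741) or YJ6 drought replicate 1 (camera p 0.564). By edgeR 0 members passed singly, over all genes and adjusted over the list alone, with 3 at an unadjusted p below 0.05, and DESeq2 called 0.

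**Figure D3:**
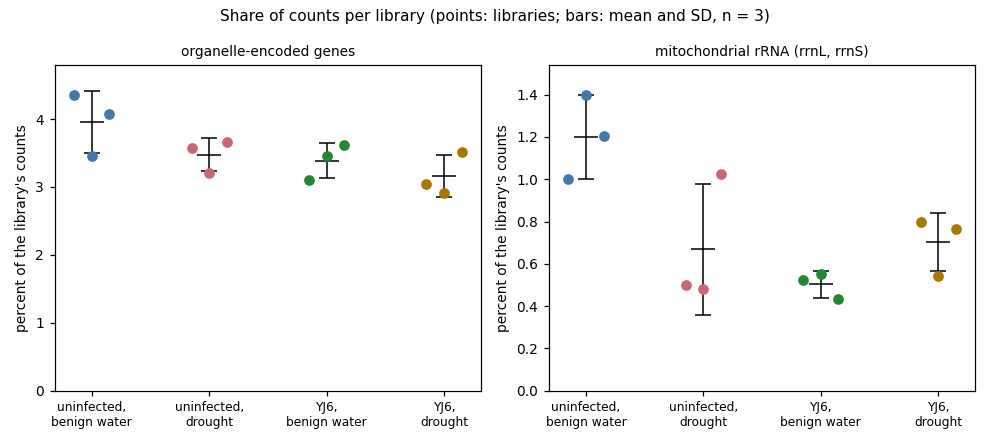
Percent of each library's counts (y axes) from organelle-encoded genes (left) and from mitochondrial rRNA (right) in the 4 groups; points are libraries, bars the mean and SD (n = 3). Mitochondrial rRNA averages 1.20% in the uninfected benign group, against 0.669%, 0.503% and 0.703% in the uninfected drought, YJ6 benign and YJ6 drought groups.

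The study's title asks whether the bacterium brings the plant into a drought-like state before any stress, so the YJ6 effect under benign water was set against the drought effect in uninfected roots. In all, 6 genes were higher in both comparisons (0.051 by independent lists), 9 were lower in both (0.065) and 0 went opposite ways. Independent lists leave out that both comparisons use the same 3 uninfected benign libraries, so they are no chance value for this overlap. LOC111899651, for example, fell by 3.00 on the log2 scale with drought and by 3.48 with YJ6 (SE 0.464, edgeR adjusted p = 0.0261). All 32 genes that changed with drought had the same sign with YJ6, and 208 of the 209 that changed with YJ6 had the same sign with drought. These genes were chosen against the same uninfected benign libraries from which the other effect and the shifts are measured, which pushes both the same way, and no chance value was computed for them. On the 209 genes the median shift from the uninfected benign mean, taken in the direction of the YJ6 effect, was 1.63 in YJ6 benign, 1.17 in uninfected drought and 1.40 in YJ6 drought libraries. On the 32 drought genes it was 2.20 in uninfected drought, 1.39 in YJ6 benign and 1.91 in YJ6 drought libraries.

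**Figure D4:**
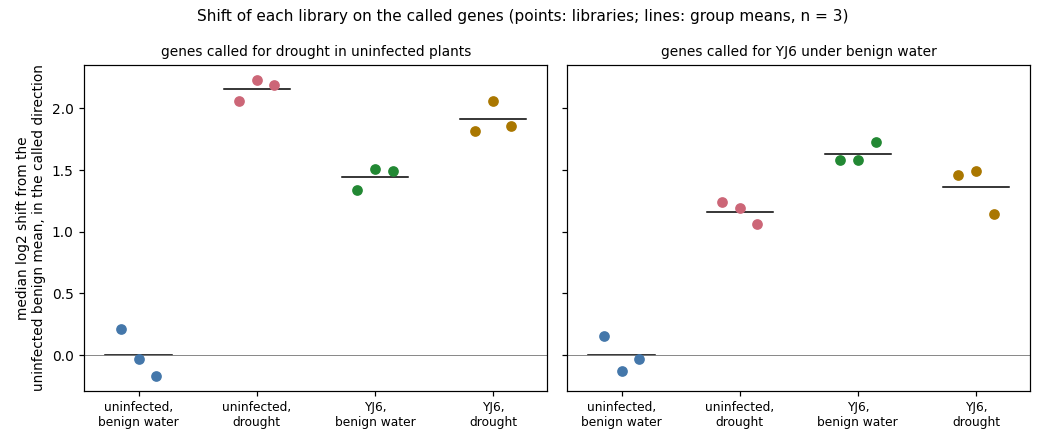
Median log2 shift of each library from the uninfected benign mean (y axis, counted in the direction in which the genes changed) over the 32 genes changed by drought in uninfected roots (left) and the 209 changed by YJ6 under benign water (right); points are libraries, lines group means (n = 3). On the 209 genes the uninfected drought libraries lie between 1.06 and 1.24 and the YJ6 drought libraries between 1.14 and 1.49; the genes were chosen against the uninfected benign libraries, from whose mean every shift is measured.

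Across all 28487 genes the log2 fold changes of the 2 comparisons correlated with Pearson's r of 0.740 and Spearman's rho of 0.723, and 78.5% had the same sign; genes are not independent replicates. Both comparisons use the same 3 uninfected benign libraries. Simulations drew these controls and both other groups from the uninfected benign means, with no gene changed. They gave a mean r of 0.512 (highest of 100 simulations 0.547) and 66.8% with the same sign. Each gene was drawn independently, so the simulated range leaves out structure that genes share within a library. Regroupings of the 9 real libraries reached an r of 0.791. The covariance of the fold changes was 0.623 in a refit made in the manner of the simulations, against a simulated mean of 0.229, a difference of 0.394. With no uninfected benign library used in both comparisons, 6 splits of these libraries gave r from 0.251 to 0.407 and a covariance from 0.353 to 0.564. Each of the 6 splits set 1 control library against the other 2. The excess over the simulated values is not by itself a shared effect.

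**Figure D5:**
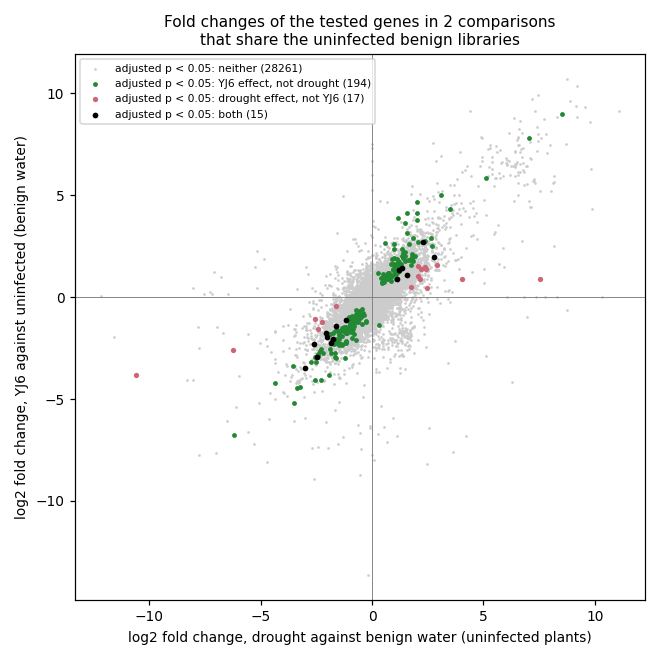
Log2 fold change of each of 28487 tested genes for drought in uninfected roots (x axis) and for YJ6 under benign water (y axis), coloured by which comparison passed an adjusted p of 0.05 in edgeR. The 15 genes that passed in both lie in the lower left and upper right; the loose cloud at the upper right is made of genes with few counts, at or near 0 in the uninfected benign libraries, whose fitted fold changes are no bounds.

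Whether drought acted differently with and without YJ6 was tested as the interaction, and 0 genes passed by edgeR's quasi-likelihood test (smallest adjusted p = 0.233, with 2457 genes at an unadjusted p below 0.05 and 1424 expected by chance); DESeq2 called 130 higher and 132 lower. The organelle list passed the test, on TMM-scaled values: its drought effect was higher in YJ6 than in uninfected roots in 140 of 174 members, with a median difference of 0.231 on the log2 scale (camera p = 5.58e-10, adjusted p = 0.0163 with an estimated correlation). The same uninfected benign libraries enter this test and the 2 comparisons in which the list was lower, so it is not independent of them. In the comparisons without these libraries the list's median was 0.0509 (drought in YJ6 roots) and -0.0121 (YJ6 under drought). By edgeR 0 of the 174 members passed singly, over all genes and adjusted over the list alone, with 17 at an unadjusted p below 0.05, and DESeq2 called 2. The median difference was 1.96 in mitochondrial rRNA, 0.465 in organelle tRNAs and 0.0335 in the mitochondrial respiratory chain and ATP synthase (12 of 21 above 0), and 0.571 in nuclear tRNA genes (85 of 100 above 0). These groups were not tested against one another. None passed camera with an estimated correlation (smallest adjusted p over 10 groups 0.288) or fry (smallest adjusted p 0.0687). Adjusted over that list alone, 4 of 4 mitochondrial rRNA entries were higher by edgeR. They carry only the symbols rrnL and rrnS and moved together (estimated correlation 0.963), so they are not separate results. Without TMM scaling, organelle genes other than rRNA went the opposite way in their mean share of all counts. It went from 2.76% ± 0.657 to 2.81% ± 0.231 with drought in uninfected and from 2.89% ± 0.302 to 2.46% ± 0.258 in YJ6 roots. The rise in uninfected roots rests on uninfected benign replicate 2, at 2.06% against 3.36% and 2.86% in replicates 1 and 3. The TMM-scaled sum of these genes went from 29800 ± 2450 to 27080 ± 3670 CPM in uninfected and from 26400 ± 2000 to 25270 ± 409 CPM in YJ6 roots. For rrnS the log2 fold change with drought was -1.36 in uninfected and 0.98 in YJ6 roots (interaction 2.34, SE 0.607, edgeR adjusted p = 0.410). Without uninfected benign replicate 1, edgeR called 29 genes for the interaction, and 1 without uninfected drought replicate 3 or YJ6 drought replicate 3.

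Averaged over uninfected and YJ6 roots, drought changed 12 genes, 6 higher and 6 lower, by edgeR's quasi-likelihood test, with LOC111913327 (mean log2 fold change 7.47, SE 0.807, edgeR adjusted p = 0.0136) and LOC111902479 (-4.01, SE 0.428, edgeR adjusted p = 0.0136) among them. The median size of the drought effect on these 12 genes was 2.45 in uninfected and 1.51 in YJ6 roots, and 10 of the 12 had the smaller effect in YJ6 roots, a difference that the interaction did not establish for any single gene. LOC111878688 was one of them, at 2.91 in uninfected and 0.90 in YJ6 roots (interaction -2.02, SE 0.506, edgeR adjusted p = 0.404). It was named for its change in uninfected roots, a choice that favours the larger effect there. DESeq2 called 370 higher and 297 lower for the mean drought effect, and edgeR 0 with a replicate block, 2 among genes of at least 10 CPM and 4 with the mitochondrial rRNA share as a covariate. The edgeR count was 190 without uninfected benign replicate 1, 22 without YJ6 drought replicate 3, 6 without YJ6 benign replicate 1, 5 without YJ6 drought replicate 1 or 2, and 4 without uninfected drought replicate 2. It was 1 without uninfected benign replicate 2 or 3 or YJ6 benign replicate 2 or 3, and 0 without uninfected drought replicate 1. Without uninfected benign replicate 1 the median size in YJ6 roots was 0.676, taken over the 190 genes called in that fit rather than over these 12. The organelle list had a median of -0.0813 for the mean drought effect (camera p = 7.74e-06), a call that was lost with an estimated correlation (adjusted p = 0.0604 with an estimated correlation).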

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

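The rRNA carry-over test, the fit with the rRNA share as a covariate, the splits without shared controls and the test of nad5 against the treatments were chosen only after the results they bear on were seen.

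In single genes, the YJ6 effect had opposite signs under benign water and drought for LOC111878688, whose interaction was -2.02 on the log2 scale, and for LOC111902479, whose interaction was 4.44. The libraries did not overlap, and edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment did not pass (adjusted p = 0.404 and 0.301). Both genes were named for the difference between uninfected drought and uninfected benign libraries, against which the 2 YJ6 effects are measured. That choice pushes the 2 effects to opposite signs and enlarges the interaction. LOC111902479 was also near the floor under drought, at 0.0696 ± 0.0254 CPM in uninfected and 0.257 ± 0.170 CPM in YJ6 libraries. The drought effect had opposite signs in uninfected and YJ6 roots, again without overlap and short of the threshold in the interaction test, for 2 rrnS entries (2.34 and 2.29) and 1 rrnL entry (1.63). Organelle genes differed in their drought effect between uninfected and YJ6 roots by a median of 0.231 on the log2 scale in camera on the interaction, on TMM-scaled values. The uninfected benign libraries enter that test and the 2 comparisons in which the list was lower, so it is not independent of them. As an unscaled share of counts, organelle genes other than rRNA went the opposite way, from 2.76% to 2.81% with drought in uninfected and from 2.89% to 2.46% in YJ6 roots. The rise in uninfected roots rests on uninfected benign replicate 2, at 2.06%. The 7 entries without a gene name, which no comparison used, held 0.803% of the counts of uninfected drought replicate 3.

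The YJ6 effect under benign water resembled the drought effect in uninfected roots, with a correlation across genes of 0.740. Noise of single uninfected benign libraries used in both comparisons is argued against as the whole cause. The lowest covariance over 6 splits without a shared library was 0.353, where such noise alone gives values around 0. A deviation common to the uninfected benign libraries would remain in every split, so the splits cannot speak to it. Chance in the grouping of the 9 libraries was not excluded, since 9 of 100 drawn regroupings (of 840), the real one and 8 others, gave a correlation as large, with a highest other value of 0.791. Carry-over of rRNA in the uninfected benign libraries stays open: uninfected drought replicate 3, the 1 other library with as much mitochondrial rRNA (1.03%, against 1.00% to 1.40%), had a median shift of 1.06 on the 209 genes, but 1 library excludes nothing. With the rRNA share as a covariate the likeness was 0.836, the 32 drought genes went from a median of 2.22 to 2.16 (SE 0.322 to 0.440) and the 209 genes from 1.64 to 1.40 (SE 0.279 to 0.451), but all calls of both comparisons ended as the SE grew. Both effects then share the covariate's error, so this decides nothing, and a response to the bacterium like that to drought, which the design names, also stays open.

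Libraries of one group spread along the first principal component, most of all YJ6 benign, from -24.2 to 70.1. Over 12 libraries, in a family of 2 relations, the component's correlation with log2 total counts was 0.0420 (two-sided permutation p = 0.899, adjusted 0.899), Spearman's rho -0.0629 (permutation p = 0.854, adjusted 0.854), 0.321 without the 2 farthest libraries, and 0.355 within groups (exact permutation p = 0.266, adjusted 0.266). With the mitochondrial rRNA share, Pearson's r was -0.671 (permutation p = 0.0186, adjusted 0.0372), rho -0.664 (permutation p = 0.0215, adjusted 0.0430), -0.600 without the 2 farthest libraries, and -0.537 within groups (exact permutation p = 0.108, adjusted 0.216). Neither within-group relation passed, and with 3 libraries per group both library depth and rRNA share stay open as sources of the spread. No biological explanation was tested, since the labels give no difference between libraries of one group.

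One nad5 entry, a mitochondrial gene of the respiratory chain, was at 0 in 7 libraries and at 358 to 650 CPM in 5. The water or bacterium treatment is argued against, since 4 of 4 groups held both libraries at 0 and libraries above 0. The assignment of reads between overlapping gene models in the authors' processing is a candidate explanation: 10 other entries were at 0 in at least 1 library and at 20 CPM or more in another of the same group. Of these, 8 were at 0 in 1 library only and 2 in 8 and 11 libraries, so most of them resemble nad5 only in part, and 2 other nad5 entries ran from 153 to 317 and from 250 to 487 CPM in all 12 libraries.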

How the results depend on the processing

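The fit with the rRNA share as a covariate, and the list tests under DESeq2 size factors and with libraries left out, were chosen only after the results were seen. Of the counts, list tests and sizes, 169 values kept their side or size and 67 moved. Another 4, all camera tests at the preset correlation, newly passed, and 2 changed direction. The latter were the organelle list for YJ6 under drought, which did not pass and was down in limma's camera without uninfected drought replicate 1 (camera p 0.741) or YJ6 drought replicate 1 (camera p 0.564). The 8 named genes that passed lost their call in 87 of 157 settings and kept it in 70; the 4 rRNA results that had not passed did so in 9 of 79. No named gene changed direction. The cause was not tested except where given.

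DESeq2 called 1132 genes for drought in uninfected roots, 60 for drought in YJ6 roots, 2407 for YJ6 under benign water, 27 for YJ6 under drought, 262 for the interaction and 667 for the mean drought effect, on which its median drought sizes were 1.58 in uninfected and 0.695 in YJ6 roots. A replicate block left 19 genes for drought in uninfected roots, 16 for YJ6 under benign water and 0 for mean drought in edgeR, with fewer residual degrees of freedom; the numbers do not pair the libraries, since 3 of 12 had their best match in their own number. The rRNA covariate left 0, 0 and 4 in the same order, a likeness of 0.836 and, over those 4 genes, a median drought size of 2.14 in uninfected roots. Without a low-count filter the likeness was 0.617, and a filter of 10 CPM left 2 genes for mean drought. Fitting only the groups compared, with fewer samples, left 0 genes for drought in uninfected roots and 2 for YJ6 under benign water. DESeq2 size factors in edgeR, and leaving out the 10 most abundant genes, kept all counts within 1.5 times.

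With 1 library left out, edgeR's count ranged from 0 to 445 for drought in uninfected roots, from 0 to 919 for YJ6 under benign water, from 0 to 190 for mean drought, from 0 to 29 for the interaction, and from 0 to 1 for both drought in YJ6 roots and YJ6 under drought. Each highest value came without uninfected benign replicate 1, except the last pair, which came without YJ6 drought replicate 3. The likeness ranged from 0.603 to 0.829. The median drought size ranged from 1.67 to 2.48 in uninfected and from 0.676 to 1.81 in YJ6 roots, over the 7 left-out libraries with enough genes to give one. Each median was taken over the genes that its own fit called for mean drought, so the ranges compare different sets of genes. For the organelle list these fits used camera at the preset correlation of 0.01 only. The camera p ranged from 0.0103 to 0.847 for drought in YJ6 roots and from 0.000757 to 0.763 for YJ6 under drought. For drought in uninfected roots, YJ6 under benign water and the interaction it was at most 2.05e-07. With an estimated correlation and all 12 libraries, the camera p of these last comparisons was 0.00982, 0.0167 and 0.0163. Libraries were not left out in that setting, so the range does not speak to it. Counting error was small at this depth for most genes, and the spread between libraries limited what could be called.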

Other observations

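The comparison of each group with the other 3 and the groups formed from gene symbols were chosen only after the data were seen.

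Set against the other 3 groups, the uninfected benign libraries differed in 1076 genes, 669 higher and 407 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (DESeq2 3179). The same comparison gave 0 for uninfected drought, YJ6 benign and YJ6 drought, with 1177, 2294 and 2051 genes at an unadjusted p below 0.05 and 69, 281 and 206 by DESeq2. Of 100 regroupings of the 12 libraries, 2 gave as many calls with the real grouping included, a share below 0.05. The comparison was chosen after the data were seen, so this share does not exclude chance. The highest other value, 1143, came from setting apart YJ6 benign replicate 3 and YJ6 drought replicates 1 and 2, the 3 libraries highest on the first principal component, which points to a structure of the samples beside the groups.

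Of the groups of organelle and tRNA genes, median log2 fold changes for drought in uninfected roots and for YJ6 under benign water were -1.17 and -1.74 for mitochondrial rRNA, -0.178 and -0.196 for the mitochondrial respiratory chain and ATP synthase, and -0.200 and -0.272 for cytochrome c maturation. Among plastid genes they were -0.231 and -0.0737 for the photosystems with cytochrome b6f and rbcL, -0.287 and -0.0883 for the NDH complex, -0.115 and -0.108 for ATP synthase, and -0.202 and -0.401 for RNA polymerase. Organelle ribosomal proteins stood at -0.140 and -0.265, organelle tRNAs at -0.297 and -0.482, and nuclear tRNA genes at -0.311 and -0.536. No group passed camera with an estimated correlation, where the smallest adjusted p over the 10 groups was 0.252 for drought in uninfected roots and 0.295 for YJ6 under benign water. At the preset correlation, by contrast, camera passed all groups for drought but plastid ATP synthase and RNA polymerase. For YJ6 it passed mitochondrial rRNA, the respiratory chain, RNA polymerase, organelle ribosomal proteins and both tRNA groups. By fry no group passed for drought (smallest adjusted p 0.121). For YJ6 fry passed mitochondrial rRNA (adjusted p 0.0243) and cytochrome c maturation, RNA polymerase, organelle ribosomal proteins and both tRNA groups (each 0.0405). Adjusted over the list alone, 4 of 4 mitochondrial rRNA entries were lower in both comparisons and higher in the interaction. These entries carry only the symbols rrnL and rrnS and moved together (estimated correlation 0.963), so they are not separate results. With YJ6 under benign water, 3 of 4 plastid RNA polymerase genes and 1 of 100 nuclear tRNA genes were lower too, adjusted in the same way. The summed nuclear tRNA genes stood at 378 ± 28.6 CPM in uninfected benign, 341 ± 31.6 in uninfected drought, 163 ± 169 in YJ6 benign and 158 ± 135 in YJ6 drought libraries (SD, n = 3). In each YJ6 group 1 library stood near the uninfected level: without YJ6 benign replicate 3 (357 CPM) the mean of that group was 65.4 CPM, and without YJ6 drought replicate 2 (313 CPM) it was 81.1 CPM.

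For the comparisons of 3 against 3 libraries, 10 splits are too few for a share below 0.05. The real split gave 32 genes for drought in uninfected roots (1 of 10 splits as large, highest other 0) and 209 for YJ6 under benign water (1 of 10, highest other 0). It gave 0 for drought in YJ6 roots (10 of 10, highest other 8) and 0 for YJ6 under drought (10 of 10, highest other 0), where every split is as large as a real count of 0. For mean drought, 1 of 100 regroupings, the real one, gave as many as the real 12, with a highest other value of 3. The regroupings mixed the water and bacterium labels freely, and the count fell to 0 without uninfected drought replicate 1. Chance is thus not excluded by this share alone. For the interaction the real count was 0, so 100 of 100 were as large by construction, which says nothing about chance. The highest other value, 5076, came from a regrouping that parted libraries at or below -19.4 on the first component from those at or above 0.253, a structure of the samples.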
